A study of Mus musculus with 20 samples.

How the data were processed

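The study sequenced RNA of whole mouse skin in 20 samples of 6 groups: control skin at 50, 100, 300 and 700 days and Sod2 conditional knockout skin at 100 and 300 days. Groups were taken from the source names and genotypes in the labels. Per the labels' protocols, total RNA was depleted of ribosomal RNA with 1 of 2 kits, without saying which sample had which, and directional libraries were read for 75 cycles from 1 end. Per the submitters' processing notes, the data were processed with HISAT2, Cufflinks and Cuffdiff against mm10, with no versions given. The gene annotation is not given in the sources used here.

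The deposited values are FPKM made by the authors, with 1 column per group and 46744 rows, each named by a gene symbol or several symbols and a locus number. How the samples of a group were combined is not given in the sources used here. Values per sample were not used here, so read depth is unknown and no interval, error or floor can be given. The comparisons had been planned, before the data were examined, as limma tests on values per sample, with a fallback for 1 value per group. The fallback was used: no test was made and no p-value is given. An exact 0 can be a failed estimate in such a table. Malat1, Ahnak, Flg2 and Rn7sk are listed at 0 in both the 50- and the 700-day controls, while Malat1 is at least 6080 FPKM in each other group. A gene at 0 is therefore only said to be listed at 0, with no fold against it.

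From this table, log2 ratios of (group FPKM + 1) were computed, which understate the change of low genes. Named genes were rows with 1 symbol, without predicted-gene, Rik, LOC, microRNA and small nucleolar RNA names and pseudogenes, 19263 in all. Of these 98.4% were found by symbol in GENCODE release M21 of GRCm38 (mm10), which gave gene classes, coordinates (1-based) and overlapping genes. The 1057 rows with several symbols were left out, and where a symbol had several rows (77 symbols, among them Junb and Flg) the row with the highest mean was used. Genes with a mean of at least 1 FPKM over the 6 groups entered, 12135 in all, of which 77 are listed at 0 in some group. A gene was counted as higher or lower at a size of at least 1.

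The 6 comparisons were old against young control skin, cKO against control skin at 300 and at 100 days, the difference of those genotype differences, and 300 against 100 days within each genotype. Comparisons stayed within a title prefix. Group values correlated (log2) at 0.926 to 0.960 within a prefix and at 0.783 to 0.899 across prefixes, and no log2 ratio was taken across prefixes. The labels do not say whether the prefixes are batches. Sex-linked transcripts differ between the groups compared, and their values stand in the report.

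Before the data were examined, 45 gene lists of skin cell types, pathways and technical markers were fixed. Each list with at least 5 measured members (43 lists) had its median log2 ratio placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside the central 95% was said to stand outside the random range. The genes named were fixed by rule as well: Sod2, Junb and Igf1, the 10 highest and 10 lowest log2 ratios with at least 5 FPKM in the higher group, and up to 4 members of each list that stood out or had a member past the size counted. Genes listed at 0 in a compared group were kept apart from the 10 highest and lowest. Shared changes were also named for genes that passed the size counted in several comparisons, and Cdkn2b, and Thbs1 in old against young control skin, were chosen after their values were seen. Not every gene that the rule names is reported here.

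The counting and the percentiles were tested on simulated group tables of 12135 genes with 200 genes changed 4-fold and log2 noise of 0.2. In tables simulated for old against young control skin 96% of changed genes were counted, and 99% for each genotype comparison. Among 200 unchanged lists, 3.5%, 6% and 3% lay outside the central 95% in the tables for old against young, cKO at 300 days and cKO at 100 days. These lists were random genes with independent noise of an assumed size. They cannot show how often lists of genes that vary together would lie outside.

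Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, rescaling to a common median and rescaling to equal totals (TPM). After seeing the data, genes listed at 0 were left out, rows with several symbols were included where 1 symbol was of a named gene, rows of 1 symbol were summed, protein-coding genes alone were used, and genes of the other-tissue and sex-linked lists were left out. Lists of lymph node, mammary epithelium and brown adipocyte genes were also written after first looking at the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.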

Results

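RNA sequencing was made from whole skin of C57BL/6 mice, an inbred laboratory strain. The 20 samples fell into 6 groups. Wild-type control skin (genotype Sod2+/+) was taken at 50 days (n = 5), 100 days (n = 2), 300 days (n = 3) and 700 days (n = 4). Skin of a conditional knockout of Sod2 (cKO, genotype Sod2-/-), which encodes the superoxide dismutase of mitochondria, was taken at 100 days (n = 3) and 300 days (n = 3). The labels do not say in which cells of the skin the gene was deleted. The values were 1 FPKM (fragments per kilobase of gene model, scaled to the mapped reads) per gene and group, computed by the authors over the samples of the group. No value per sample was used here, so there is no replicate spread, no error and no test for any value below. A gene was counted as higher or lower where its log2 ratio of (FPKM + 1) had a size of at least 1, among 12135 named genes with a mean of at least 1 FPKM. The number of reads behind each group is unknown. FPKM summed to between 496936 in the 700-day controls and 692242 in the 300-day cKO.

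Sod2, Junb and Igf1 came first. Sod2 stood at 17.6 FPKM in cKO skin and 27.7 in control skin at 100 days, and at 16.8 against 23.5 FPKM at 300 days, log2 ratios of -0.63 and -0.46. The transcript was thus lower in both groups labelled cKO, by less than the size set for counting. A gene-level value sums over exons, and the deleted exons are not given in the labels. In the 50-day and 700-day controls Sod2 was 12.7 and 11.5 FPKM. Junb, a subunit of the AP-1 transcription factor named in the series title, was 33.9 FPKM in cKO against 20.1 in control skin at 100 days (log2 ratio 0.73). At 300 days it was 26.2 against 24.5 FPKM (0.09), and it was 30.2 FPKM at 700 days against 27.8 at 50 days (0.11). Igf1, the growth factor insulin-like growth factor 1, was lower in cKO skin at both ages, at 15.9 against 45.7 FPKM at 100 days (log2 ratio -1.47) and 11 against 30.8 FPKM at 300 days (-1.41). It was 5.66 FPKM at 700 days and 11.6 at 50 days (-0.92), just short of the size counted. In the GRCm38 (mm10) assembly Sod2 lies on chromosome 17 from 13006846 to 13040063, Junb on chromosome 8 from 84974484 to 84978718 and Igf1 on chromosome 10 from 87858265 to 87937042. The annotated span of Junb overlaps that of Prdx2, a protein-coding gene, and that of Igf1 overlaps an antisense transcript.

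**Figure D1:**
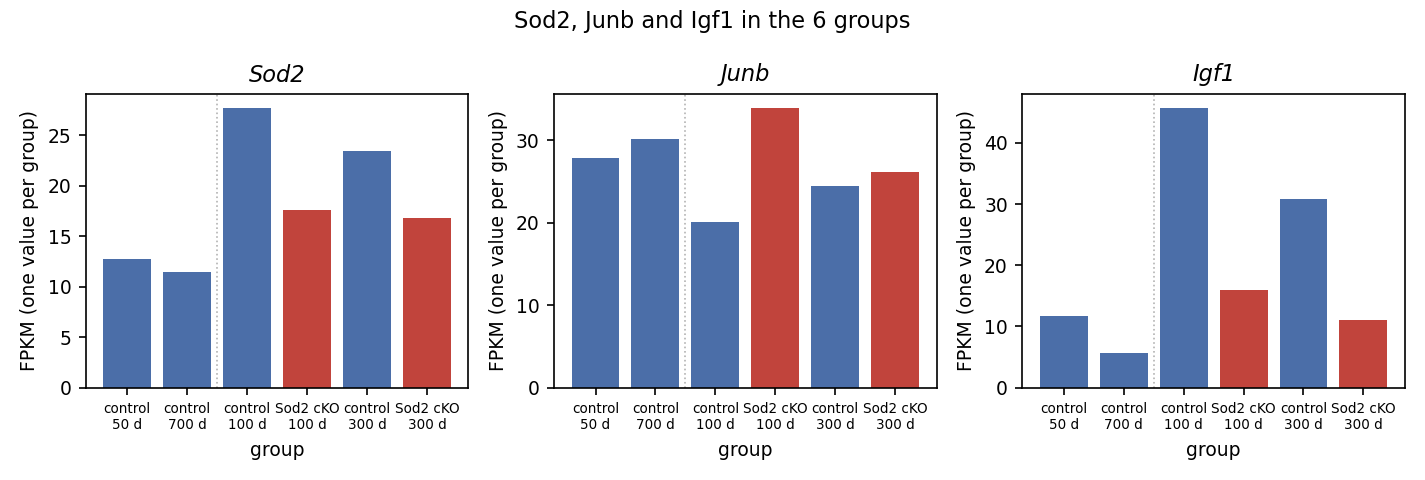
FPKM of Sod2, Junb and Igf1 (vertical axis from 0, 1 value per group) in the 6 groups on the horizontal axis, controls in blue and Sod2 cKO in red, with a dotted line between the 2 sets of library titles. Igf1 is 15.9 against 45.7 FPKM in cKO and control skin at 100 days and 11 against 30.8 FPKM at 300 days.

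Sex-linked transcripts differed between the groups of each of these comparisons. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay between 14.7 and 45.1 FPKM in the 700-day controls and in both cKO groups. In the 50-, 100- and 300-day controls they lay at or below 0.347 FPKM. Xist, the transcript of the inactive X chromosome, was 2580, 1141 and 2187 FPKM in the 50-, 100- and 300-day controls, and 3.69, 4.92 and 17.2 FPKM in the 700-day controls and the cKO groups at 100 and 300 days. Its row in the table also carries the symbols of a pair of small predicted genes. Age in the first comparison, and genotype in the cKO comparisons, therefore ran together with this sex-linked difference.

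The first comparison asked how skin of 700-day control mice differed from that of 50-day control mice. Skeletal muscle, adipocyte and some collagen genes were lower in the old group, and genes that keratinocytes switch on under stress were higher. In all, 71 genes were higher and 394 lower. All 18 measured skeletal muscle genes were lower, with a median log2 ratio of -5.08. Tnnc2, Ckm and Tnnt3, which encode parts of the contractile apparatus and the creatine kinase of muscle, were 6.18, 9.17 and 7.09 FPKM at 700 days against 374, 436 and 336 FPKM at 50 days. The annotated span of Tnnc2 overlaps that of Ube2c. Of 18 adipocyte genes 13 were lower and none higher (median -1.46). The adipokine Adipoq was 9.73 against 41.6 FPKM, Retn 12.2 against 65.4 FPKM and Car3 68.7 against 437 FPKM. The skeletal muscle and adipocyte lists thus moved in the same direction in this comparison.

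Some dermal matrix genes were lower in the old group as well. Of 19 collagen chains 5 were lower and none higher (median -0.82). Col14a1 was 0.871 against 7.32 FPKM, and the basement membrane chains Col4a1 and Col4a2 were 22.1 against 49.1 FPKM and 6.69 against 16.1 FPKM. Among 27 genes of elastic fibres, proteoglycans and other matrix, 6 were lower and 1 higher (median -0.41). Mfap5, Vcan and Fbn1 were lower, at 2.24 against 9.0, 2.32 against 7.54 and 9.11 against 22.2 FPKM, and Thbs1 was higher at 29.2 against 13 FPKM. Of 16 fibroblast markers only Fap passed the size counted, at 2.93 against 6.93 FPKM, and the median of the list was -0.39.

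Of 14 epidermal stress genes 10 were higher at 700 days and none lower (median 1.55). The keratin Krt16 was 36.0 against 3.71 FPKM, its relative Krt6b 19.0 against 1.72 FPKM and the calcium-binding protein gene S100a9 10.4 against 0.448 FPKM. In the differentiated epidermis list 4 of 27 genes were higher and none lower (median 0.34). Krt1 was 1112 against 395 FPKM, Krt2 9.63 against 0.767 FPKM and Hrnr 59.1 against 20.9 FPKM. Of 14 basal keratinocyte genes only Krt14 passed the size counted, at 1391 against 604 FPKM, and the median of the list (0.07) lay inside the random range. Krt6b has near-identical relatives, so its share of their reads is uncertain. The immediate early and heat shock list, a marker of tissue handling, had a median of 0.16 (percentile 99.7), above the random range, with none of 18 genes past the size counted.

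Hair shaft and inner root sheath genes were lower in 10 of 35 cases and higher in none (median -0.65), among them Krt35 at 3.0 against 16.1 FPKM and Krt31 at 8.78 against 25.3 FPKM. Of 12 melanocyte genes 4 were lower (median -0.69), with the pigment enzyme Tyrp1 at 2.48 against 11.8 FPKM. Of 18 macrophage and monocyte genes 6 were lower (median -0.77). The scavenger receptor Cd163 was 3.44 against 9.31 FPKM and the complement component C1qb 4.53 against 11.5 FPKM. Of 17 IGF signalling genes none passed the size counted. Their median was -0.25, at percentile 1.24 of random lists and at 2.93 with a pseudocount of 0.1. None of 10 AP-1 genes passed it either.

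Among single genes, Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, had the largest log2 ratio of the comparison (8.52), at 387 FPKM at 700 days and 0.0545 at 50 days. It lies on chromosome 4 from 89274471 to 89294653, with no other annotated gene overlapping it. With 1 value per group and no reads used here, whether this is a true level of the transcript could not be checked. Its level was at most 3.45 FPKM in the other 4 groups, and its neighbour Cdkn2b was 7.99 against 4.93 FPKM. Besides Cdkn2a, the collagenase gene Mmp13 passed the size counted among 17 senescence-related genes (median 0.35), listed at 0 at 50 days and 1.44 FPKM at 700 days. The defensin Defb8 was 76.1 against 0.139 FPKM, the complement gene C7 11.3 against 0.240 FPKM and Slurp2 23.9 against 1.19 FPKM. Rprl3, annotated as a ribozyme, was 57.3 against 0.123 FPKM. Lars2 and mt-Rnr1 were listed at 0 at 700 days and at 2711 and 13775 FPKM at 50 days, for which no fold is given.

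Of 43 lists with at least 5 measured members, 7 lay above and 15 below the central 95% of random lists matched on expression. Genes of a list vary together, so this percentile describes these groups and is no test. With a pseudocount of 0.1 the count for old against young control skin was 134 genes higher and 770 lower.

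The second comparison asked how Sod2 cKO skin differed from control skin at 300 days. Lymphocyte, antigen presentation, macrophage and adipocyte genes were lower in cKO than in control skin, and epidermal stress genes and some hair shaft genes were higher. In all, 222 genes were higher and 616 lower. All 8 measured B and plasma cell genes were lower (median -2.96), as were 11 of 14 T and NK cell genes (median -1.78). The immunoglobulin light chain Igkc was 1.84 FPKM in cKO and 240 in control skin, the B cell receptor component Cd79b 0.118 against 14.7 FPKM and the T cell receptor constant region Trac 0.439 against 24.8 FPKM. Ccl5, a chemokine of T cells, was 0.756 against 24.1 FPKM. Cr2, Ighd, Iglc3 and Cd22 were also among the lowest ratios, at 0.488, 0.194, 0.206 and 0.125 FPKM in cKO and 30.7, 33.6, 40.1 and 14.5 FPKM in control skin. These transcripts were high in the 300-day controls only. Igkc was 5.76 FPKM in control skin at 100 days, and 0.294 and 2.38 FPKM at 50 and 700 days.

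Genes of antigen presentation and macrophages moved the same way. Of 10 dendritic, Langerhans and MHC class II genes 8 were lower (median -1.54), including H2-Aa at 38.5 against 132 FPKM and H2-DMa at 3.04 against 20.1 FPKM. Of 18 macrophage and monocyte genes 10 were lower (median -1.07), with C1qa at 15.7 against 44.5 FPKM and the chemokine receptor Ccr2 at 2.98 against 12.3 FPKM. The type I interferon response list had a median of -0.50 and 1 of 21 genes past the size counted, Cxcl9 at 1.86 against 4.99 FPKM.

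Of 18 adipocyte genes 13 were lower and none higher (median -1.22). Lep, the hormone leptin, was 4.37 against 17.5 FPKM, the lipid droplet coat Plin1 42.7 against 124 FPKM and the lipase Pnpla2 40.2 against 118 FPKM. Of 12 fatty acid synthesis genes 3 were lower (median -0.87), with Scd1 at 521 against 1176 FPKM and Fasn at 212 against 474 FPKM. The skeletal muscle list had a median of 0.20 in this comparison. The simple epithelial keratin Krt19 and Ltf, a secreted iron-binding protein, were 0.684 against 33.4 FPKM and 0.264 against 24.2 FPKM.

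Of 14 epidermal stress genes 8 were higher and 2 lower (median 1.17). Krt16 was 61.8 in cKO against 5.24 FPKM in control skin and Krt6b 47.9 against 0.167 FPKM. The stefin genes Stfa1 and Stfa3 were 33.8 and 48.7 FPKM in cKO and listed at 0 in the control, and their relative BC100530 was 132 against 1.41 FPKM; near-identical copies can share reads. Of 27 differentiated epidermis genes 5 were higher (median 0.42), among them Flg at 295 against 42.6 FPKM, Casp14 at 26.1 against 5.86 FPKM and Krt1 at 299 against 94.9 FPKM. Flg is spread over 8 rows of the table, of which the highest was used. The protease Klk6 was 49.1 against 2.51 FPKM. Of 14 basal keratinocyte genes 2 were higher (median 0.59), among them Krt14 at 882 against 328 FPKM. Of 27 proliferation genes 4 were higher and none lower (median 0.43), with Bub1 at 11.8 against 4.25 FPKM.

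Hair shaft and inner root sheath genes were higher in 10 of 35 cases (median 0.75), such as Krt36 at 13.9 against 4.82 FPKM and Krt33b at 146 against 59.0 FPKM. Of 19 collagen chains 2 were higher and 1 lower. Col1a1 was 544 against 170 FPKM and Col1a2 545 against 242 FPKM, and Col5a3 was lower at 7.14 against 15.4 FPKM (median of the list -0.16, inside the random range). Of 17 senescence-related genes 5 were higher and 1 lower (median 0.32), including Mmp13 at 6.88 against 0.0159 FPKM, Il1b at 8.18 against 0.488 FPKM and Cdkn2a at 3.45 against 0.178 FPKM. The percentile of that median was 99.9, and it was 97.3 with no filter on low values and 89.7 without genes listed at 0. Of 10 AP-1 genes Fos and Fosb were higher, at 18.0 against 6.43 and 2.35 against 0.609 FPKM, and Batf lower at 0.267 against 3.45 FPKM. The tissue handling list stood above the random range in the same comparison (median 0.38, percentile 99.9), with 1 of 18 genes higher and 1 lower. Of 17 IGF signalling genes 3 were lower and 1 higher (median -0.36). Igfbp6 was 11.7 against 33.6 FPKM and Igfbp2 14.0 against 6.19 FPKM. In the circadian clock list (median -0.56) Dbp was 8.79 against 38.0 FPKM, Tef 59.0 against 169 FPKM and Arntl 10.9 against 4.88 FPKM.

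Of the 43 lists 10 lay above and 17 below the random range at 300 days. With genes of at least 5 FPKM the count was 147 higher and 273 lower.

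The third comparison asked the same of skin at 100 days. Adipocyte and fatty acid synthesis genes and some collagen and other matrix genes were lower in cKO than in control skin, while some hair shaft and pigment cell genes were higher. In all, 266 genes were higher and 519 lower. Of 18 adipocyte genes 17 were lower (median -1.73), among them Lep at 3.73 against 36.1 FPKM, Plin1 at 30 against 170 FPKM and the receptor Adrb3 at 3.52 against 19.9 FPKM. Of 12 fatty acid synthesis genes 8 were lower (median -1.30), with Scd1 at 372 against 1985 FPKM and Fasn at 214 against 769 FPKM. Of 18 skeletal muscle genes 7 were lower (median -0.88), with Myh4 at 389 against 1143 FPKM. Myl2, a myosin light chain of heart and slow muscle, was higher at 28.7 against 1.05 FPKM, and its annotated span overlaps that of Ccdc63.

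Among the 10 lowest ratios, genes listed at 0 left out, were several transcripts of simple epithelia and secretory glands, a theme for which no list had been fixed. Krt8, Krt18 and Krt19, keratins found in simple epithelium, were 0.472, 2.67 and 1.21 FPKM in cKO skin and 55.8, 81.3 and 136 FPKM in control skin. Wfdc2 and Aqp5, found in secretory glands, were 0.468 against 45.4 FPKM and 0.107 against 19.0 FPKM. Ltf was 1.05 against 55.5 FPKM, the oxytocin receptor Oxtr 1.25 against 57.9 FPKM, Dmbt1 0.913 against 45.3 FPKM and Ido1 0.101 against 20.7 FPKM.

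Of 19 collagen chains 7 were lower and none higher (median -0.77). Col15a1 was 29.2 against 116 FPKM, Col6a3 18.9 against 70.6 FPKM and Col5a2 31.7 against 87.8 FPKM. Of 17 collagen processing genes 4 were lower (median -0.56), with the collagen chaperone Serpinh1 at 24.5 against 74.6 FPKM. Among 27 other matrix genes 5 were lower and 1 higher (median -0.55), including Postn at 62.1 against 281 FPKM and Lum at 18.0 against 64.4 FPKM, with Thbs1 higher at 45.8 against 20.1 FPKM. Of 17 IGF signalling genes 5 were lower and 1 higher (median -0.53). Igfbp5 was 32.0 against 88.0 FPKM and Igfbp3 163 against 48.0 FPKM. Of 37 nuclear genes of oxidative phosphorylation none passed the size counted, and their median was -0.46. Ndufb5 was 68.2 against 117 FPKM and Cox6c 281 against 470 FPKM. The oxidative phosphorylation list also lay below the random range in the cKO at 300 days and in old against young control skin. Its median was -0.18 in each, with no gene past the size counted.

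Of 35 hair shaft and inner root sheath genes 15 were higher and none lower (median 0.95), with Krt72 at 575 against 102 FPKM, Krt28 at 523 against 123 FPKM and Tchh at 957 against 247 FPKM. Of 12 melanocyte genes 6 were higher (median 1.00), with the pigment enzyme Tyr at 17.4 against 6.14 FPKM and Pmel at 30.5 against 13.5 FPKM. In the hair follicle stem cell list Fgf18 was higher at 6.09 against 1.39 FPKM (median 0.41). Basal keratinocyte genes had a median of 0.36 and none past the size counted. Proliferation genes had a median of 0.45, above the random range, with none of 27 past the size counted. Of 14 epidermal stress genes 5 were higher and 2 lower (median 0.55). S100a8 was 21.4 against 2.53 FPKM and Sprr1a 118 against 43.5 FPKM, while Stfa3 was 0.202 against 7.78 FPKM. The percentile of that median was 100, and it was 90.7 with no filter on low values.

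The AP-1 genes Fos and Fosb were lower in cKO skin at this age, at 6.76 against 21.8 and 0.397 against 5.07 FPKM. Of the 18 tissue handling genes 2 were lower and none higher, with a median of 0.17 inside the random range. Of 21 type I interferon response genes 4 were lower (median -0.57), with Ifi27l2a at 100 against 345 FPKM. The B and plasma cell list had 1 of 8 genes lower and a median inside the random range (-0.23), and no T and NK cell gene of 14 passed the size counted. The macrophage and monocyte list lay below the random range, with 3 of 18 genes lower (median -0.48). So did the dendritic, Langerhans and MHC class II list (median -0.62), with none of 10 genes past the size counted. Among single genes, Cytl1 was 40.6 against 1.54 FPKM, the B cell chemokine Cxcl13 17.7 against 0.152 FPKM, Ankrd1 7.17 against 0.229 FPKM and Ifitm1 19.8 against 2.03 FPKM.

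Of the 43 lists 11 lay above and 15 below the random range at 100 days. Rescaled to equal totals, the median of all genes moved by -0.12 and 23.0% of counted genes were higher, against 33.9% as deposited.

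**Figure D2:**
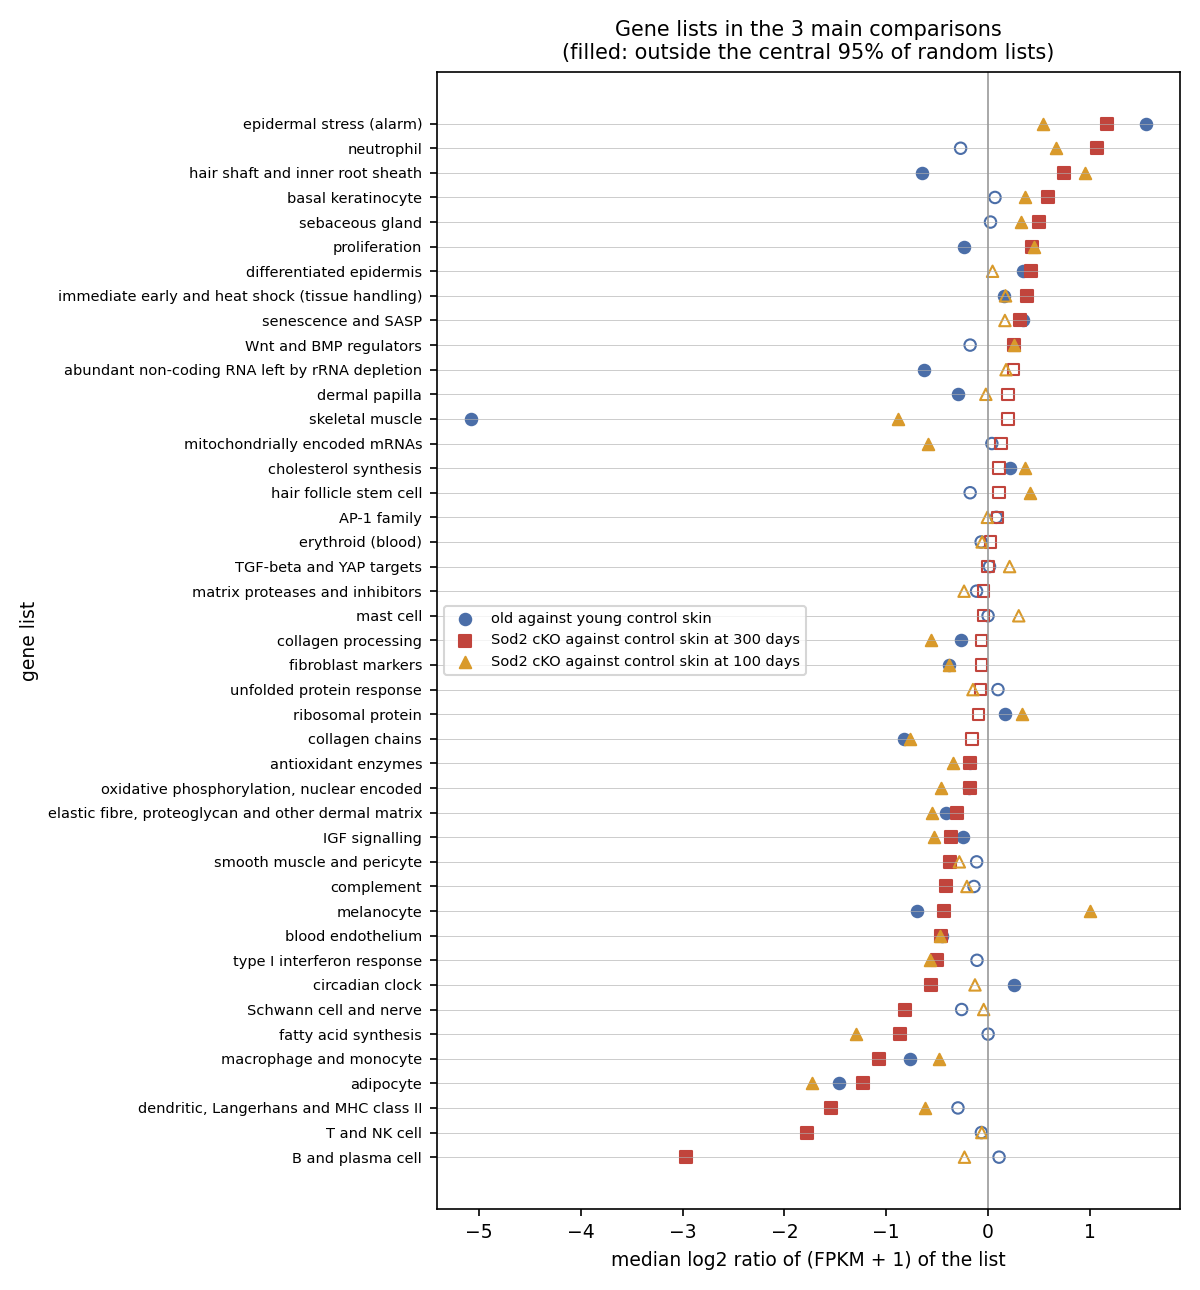
Median log2 ratio of (FPKM + 1) on the horizontal axis for each gene list on the vertical axis, in old against young control skin (circles) and in Sod2 cKO against control skin at 300 days (squares) and at 100 days (triangles). Filled symbols lie outside the central 95% of random lists. The adipocyte list lies at -1.46, -1.22 and -1.73, and the skeletal muscle list at -5.08, 0.20 and -0.88.

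The genotype differences at 300 and 100 days were then set against each other, which removes a difference by sex that is equal at both ages. In this difference 464 genes were higher and 570 lower. Some collagen genes were relatively higher in cKO skin at 300 days, with 5 of 19 chains higher, none lower and a median of 0.62. Col1a1 and Col1a2 stood at 544 and 545 FPKM in the 300-day cKO against 151 and 166 FPKM in the 100-day cKO, and at 170 and 242 FPKM in the 300-day controls. The epidermal stress list had a median of 0.95, with 7 of 14 genes higher and 4 lower. Krt6b (5.12) and Krt16 (2.31) were among those higher, as was Stfa3, which is listed at 0 in the 300-day controls. Flg (3.36) and BC100530 (6.90) were also among the highest, and the AP-1 genes Fosb (3.18) and Fos (2.91) changed sides between the ages. In this difference 3 of 18 immediate early and heat shock genes, the marker of tissue handling, were higher, with a median of 0.09 inside the random range. Skeletal muscle genes were higher in 8 of 18 cases (median 0.95). The largest stood at 11.3 and came from a gene with a log2 ratio of -10.1 between 300 and 100 days in control skin.

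The lowest values of that difference came from lymphoid genes, including Cxcl13 (-5.65), Igkc (-5.18) and Ighd (-4.70), and all 8 B and plasma cell genes were lower. Part of the Cxcl13 value came from its higher level in cKO than in control skin at 100 days. Of 12 melanocyte genes 8 were lower (median -1.52), with Trpm1 at -2.20 and Pmel at -1.80. Hair shaft and inner root sheath genes were lower in 10 of 35 cases, but their median of -0.09 lay inside the random range. Of the 43 lists 11 lay above and 10 below the random range. Rescaled to equal totals, 56.3% of counted genes were higher instead of 44.9%, and the median of all genes moved by 0.10.

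Between 100 and 300 days none of the 4 Y-linked genes passed the size counted in either genotype. Xist was 1141 FPKM at 100 days and 2187 at 300 days in control skin, and 4.92 and 17.2 FPKM in cKO skin. In control skin 415 genes were higher and 123 lower at 300 days. Immune genes made up the top. Of 8 B and plasma cell genes 7 were higher (median 3.04), as were 11 of 14 T and NK cell genes (median 2.15), 8 of 18 macrophage and monocyte genes (median 0.96) and 9 of 21 type I interferon response genes (median 0.94). Lyz2 was 150 FPKM at 300 days against 54.5 at 100 days, Isg15 13 against 3.30 FPKM and Cd2 26.0 against 0.638 FPKM. The lowest ratios belonged to Ido1 at 2.13 against 20.7 FPKM, Dmbt1 at 5.74 against 45.3 FPKM and Aqp5 at 3.29 against 19.0 FPKM. The adipocyte list had a median of -0.51 with 2 of 18 genes lower, Adrb3 at 9.27 against 19.9 FPKM and Lep at 17.5 against 36.1 FPKM. Rescaled to equal totals, the median of all genes moved by -0.18 and 61.0% of counted genes were higher instead of 77.1%.

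In cKO skin 288 genes were higher and 175 lower at 300 days. Type I interferon response genes were again higher in 11 of 21 cases, with a median of 1.00, and Ifit1 was 6.93 against 1.01 FPKM. Epidermal stress genes were higher in 8 of 14 cases and lower in 3 (median 1.16), with Stfa3 at 48.7 against 0.202 FPKM. Melanocyte genes were lower in 7 of 12 cases (median -1.21), with Dct at 21.9 against 58.3 FPKM, and mast cell genes in 4 of 8 (median -0.98), with the protease Cma1 at 4.60 against 16.7 FPKM. Hair shaft and inner root sheath genes were lower in 8 of 35 cases (median -0.37), such as Krt27 at 254 against 670 FPKM. Igfbp3 was 36.3 against 163 FPKM. Across 12135 genes, the age differences in control and cKO skin had a Spearman correlation of 0.0300 and a Pearson correlation of 0.00598. In both genotypes 43 genes were higher and 5 lower, where independent lists would share 9.85 and 1.77. Another 16 genes were higher in control and lower in cKO skin and 12 the reverse, where independent lists would share 5.98 and 2.92.

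**Figure D3:**
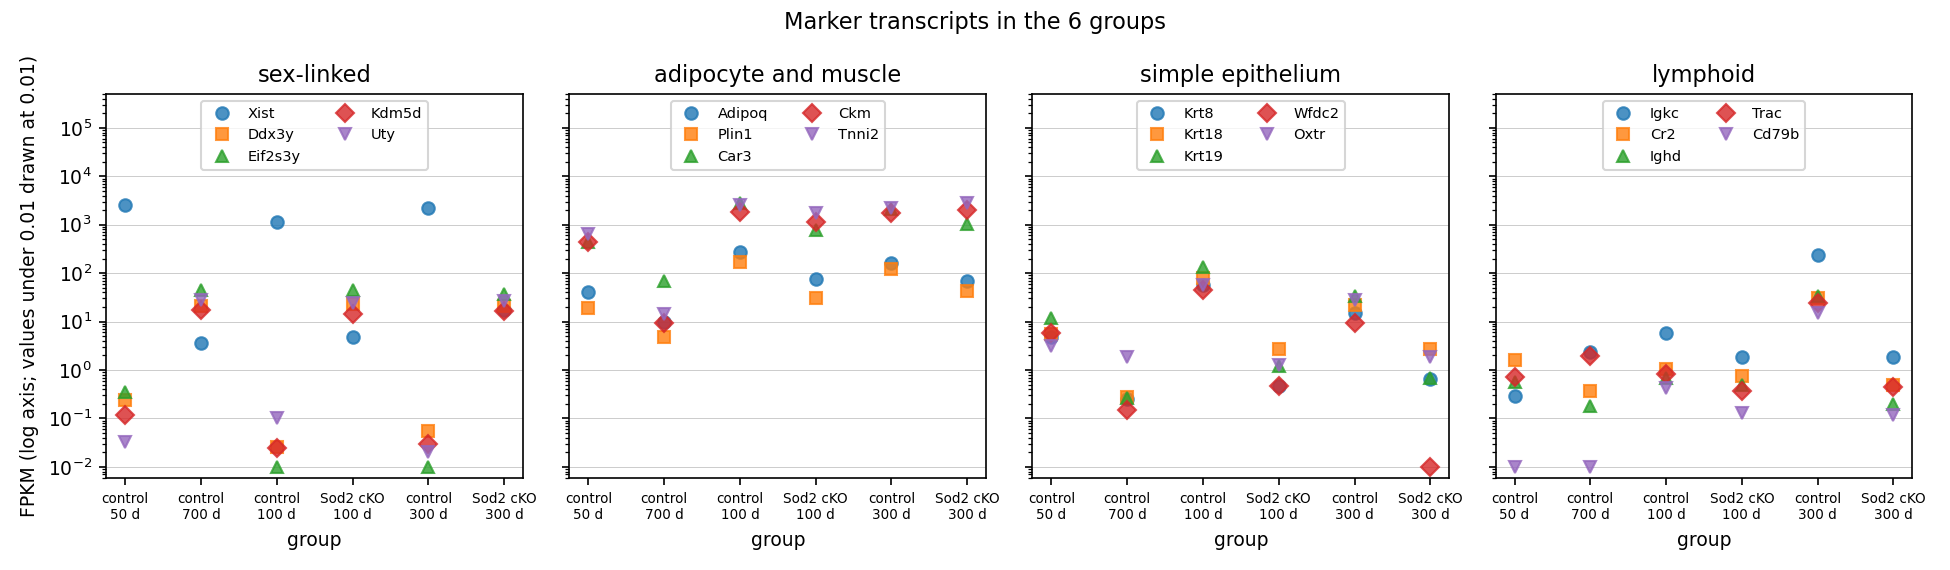
FPKM on a log axis (values under 0.01, zeros included, drawn at 0.01) of sex-linked, adipocyte and muscle, simple epithelial and lymphoid transcripts in the 6 groups on the horizontal axis, 1 point per gene and group. Xist is 2580, 1141 and 2187 FPKM in the 50-, 100- and 300-day controls, and Igkc reaches 240 FPKM in the 300-day controls.

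The likeness of the cKO and the age differences was described across genes, which are not independent replicates. Old against young control skin and cKO against control skin at 300 days had a Spearman correlation of 0.173 and a Pearson correlation of 0.165. Of the 71 genes higher with age, 33 were also higher in cKO skin at 300 days, where independent lists would share 1.30. Of the 394 genes lower with age, 67 were lower there, where independent lists would share 20. In the opposite direction, 23 genes lower with age were higher in cKO skin at 300 days, where independent lists would share 7.21, and 4 higher with age were lower, against 3.60. Krt16, Klk6, C7 and Thbs1 were among the genes higher in both, and Adipoq, Plin1 and Car3 among those lower in both. For the cKO at 100 days the Spearman correlation with age was 0.238 and the Pearson correlation 0.308, and 22 genes were higher and 103 lower in both, where independent lists would share 1.56 and 16.9. There, 19 genes lower with age were higher in cKO skin and 4 higher with age were lower, against 8.64 and 3.04. The genotype differences at the 2 ages correlated at 0.382 (Spearman) and 0.354 (Pearson), with 38 genes higher and 154 lower in both, where independent lists would share 4.87 and 26.3. Opposite directions held for 11 genes higher at 300 days and 13 lower at 300 days, against 9.49 and 13.5. No group entered both sides of any of these pairs, and each of the 3 comparisons ran from Xist-high to Y-linked-high groups.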

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

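The tests of sex, of a stress response and of the deep skin layers were chosen after the result was seen. Those of lymph node and mammary tissue were set before their genes' values were seen, except that the 0.1 FPKM floor for a measured gene was set with the test. Among those genes, Ms4a1, Cd5 and Wnt4 were also members of the fixed lists.

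Rows of the table that carry several symbols were outside the comparisons, and the highest of them with 1 protein-coding symbol show a signal above the group compared with. Of 486 such rows, 7 were higher and 14 lower in old against young control skin, 18 and 39 in the cKO at 300 days, and 16 and 22 at 100 days. Rnf225 had a log2 ratio of 2.46 (148 against 26.1 FPKM) and Ampd3 one of 2.04 in old against young control skin. In cKO against control skin at 300 days Maml2 stood at 2.52 and Pyurf at 2.18. At 100 days Grm8 stood at 4.49 (33.7 against 0.545 FPKM) and Prmt2 at 3.33. Each row also carries a small or predicted RNA, so the reads cannot be given to the named gene.

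The Y-linked genes were high and Xist low in the 700-day controls and both cKO groups, and the reverse held in the groups they were compared with. In all 3 comparisons each of 4 Y-linked genes was at least 16-fold higher, or listed at 0 in the low group (Eif2s3y at 100 and 300 days), and Xist at least 16-fold lower, as male against female groups would give. Some samples of the other sex within a group would leave at least 10% of the high level in the low groups, and the highest such share was 1.51%, which argues against it for these 6 groups. A candidate explanation for part of the age and genotype differences is thus sex, which the labels do not give and which has the same layout as the groups. It cannot be separated from age or genotype in 2-group comparisons of this table.

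Most of the lymphoid transcripts named above were high in the 300-day controls alone, an exception being Cxcl13, which was high in cKO skin at 100 days. A lymph node list of 20 measured genes (at least 0.1 FPKM in a group) was written after the lymphoid pattern was seen, without sight of their values. Ms4a1 and Cd5 among them were, however, also members of the fixed B and plasma cell and T and NK cell lists. Of the 20, 18 (90%) were highest in the 300-day controls and at least 2-fold above every other group. Ccl19 and Madcam1, genes of the stroma and vessels of lymph nodes, were not, at 0.253 and 0.196 FPKM in the 300-day controls. Chst4 and Fut7, also low there at 0.518 and 1.25 FPKM, were among the 18. Most of the 18 are lymphocyte genes that an infiltrate would raise too, so this share cannot tell a lymph node from an infiltrate. The most abundant were Cd52 at 67.7 FPKM and Cd37 at 15.5 FPKM, and Glycam1, made by the high endothelial venules of lymph nodes and already seen, was 73.6 FPKM there and at most 0.515 elsewhere. For an epidermal stress response, the list had a median of 0.13 (quartiles 0.03 and 0.35) between 300 and 100 days in controls. A median of 1 was needed, and a median under 0.5 was set as speaking against it. Of its 14 genes 1 was higher and 2 lower, with members from -3.13 to 1.5. This argues against a rise of the list as a whole, not of single members. Lymph node tissue in some 300-day control samples may account for the lower lymphocyte genes of the cKO at that age, while an immune infiltrate in the skin, and age, sex or genotype, stay open as untested.

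Adipocyte genes were lower in the 700-day controls and in cKO skin at both ages. Less of the deep layers in the sample would lower the muscle below the fat as well. Its list had medians of -5.08 at 700 days and -0.88 in the cKO at 100 days, so this stays open for both; the adipocyte median itself (-1.46) was asked for at 700 days but only 50% of it (-0.86) at 100 days, where the whole of it (-1.73) was not reached. At 300 days the muscle median was 0.20 and its lowest gene stood at -0.51, where a median of -0.61 was needed. That argues against less of the muscle layer there, but the muscle list cannot decide on fat lying below that layer. Mammary gland with its fat in the controls could not be decided: 26.3% of 19 mammary genes at 100 days and 47.4% at 300 days were at least 2-fold lower or listed at 0 (1 and 5 genes) in cKO skin, between the bounds of 25% and 75%, and effects of age, genotype and sex also stay open.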

How the results depend on the processing

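Some alternatives were chosen after seeing the data: leaving out genes listed at 0 or genes of the other-tissue and sex-linked lists, including rows with several symbols, summing rows of 1 symbol and using protein-coding genes alone. No paired analysis was possible because the table holds 1 value per group and none per sample. For the same reason leaving out replicates, quality weights, other estimates of the spread, camera and fry gave no value and were not run. Read depth is unknown and limits low genes most.

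Counts of genes past the size counted depended on the pseudocount and the filter. A pseudocount of 0.1, under which low genes give larger ratios, gave 904 genes for old against young control skin (465 as reported). It gave 1276 for Sod2 cKO against control skin at 100 days (785) and 838 for Sod2 cKO skin at 300 days against 100 days (463). A mean of at least 5 FPKM, with fewer genes, gave 420 for Sod2 cKO against control skin at 300 days (838) and 502 at 100 days. It gave 223 for control skin at 300 days against 100 days (538), 261 for the same ages in cKO skin, and 536 for the difference of the genotype differences (1034). The other alternatives kept each count of genes within 1.5 times, as did the 6 alternatives run for the numbers of lists. Igf1 in old against young control skin passed the size counted at a pseudocount of 0.1 (-1.03). The Spearman correlation of the genotype differences, 0.382, was 0.397 with genes of at least 5 FPKM. That lay outside a 95% interval over genes, which treats genes as independent replicates and so measures no spread between samples. The senescence list reversed in the difference of the genotype differences, from 0.32 to -0.080 with a pseudocount of 0.1, -0.19 with no filter and -0.29 without genes listed at 0. The causes of these last 2 changes were not tested. Over the lists and the 6 alternatives run for them, 1491 values kept their standing, 20 lost it and 28 gained it. Of named genes, under a pseudocount of 0.1, both rescalings and summed rows, 3047 values stayed on their side of the size counted, 33 lost it, 32 gained it and none past it changed sign.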

Other observations

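The overlap of all 3 comparisons and the added lists were chosen after the result was seen, though the lymph node and mammary lists hold parts written without sight of their values. Across the 3 main comparisons, 15 genes were higher in all and 38 lower in all, where independent lists would share 0.0285 and 0.855. Besides the 4 Y-linked genes, those higher included the stress genes Krt16, S100a8 and Sprr1b, the protease Klk6, the complement gene C7, the defensin Defb8, Thbs1 and Cdkn2a. Of these, Eif2s3y and Defb8 are listed at 0 in the 100- and 300-day controls, and Cdkn2a in the 100-day controls. Krt16 was 36.0, 61.8 and 8.81 FPKM in the 700-day controls and the cKO groups at 300 and 100 days, and 3.71, 5.24 and 3.84 FPKM in the groups they were compared with. C7 was 11.3, 12.8 and 4.19 FPKM against 0.240, 0.298 and 0.204 FPKM. Those lower in all held the adipocyte genes Adipoq, Cfd, Cidec, Lep, Plin1 and Thrsp, the simple epithelial keratins Krt8, Krt18 and Krt19, and Retnla, a secreted product of alternatively activated macrophages, at 0.340, 25.2 and 17.4 FPKM against 15.6, 87.2 and 45.3 FPKM. Because the 3 comparisons share the layout of Xist and the Y-linked genes, this overlap does not separate age or genotype from sex.

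A list of 13 genes of glandular epithelium was chosen because their values had been seen, and Ltf among them is also on the fixed neutrophil list. It was lower in all 13 cases in cKO skin at both ages, with medians of -4.18 at 100 days and -2.78 at 300 days, and in 7 of 13 at 700 days (median -1.20). The 10 measured members of the list written without sight of their values had medians of -0.27, -0.36 and 0.03 in these comparisons. The brown fat gene Ucp1 was 2.49 against 22.6 FPKM in cKO and control skin at 100 days and 11 against 29.2 FPKM at 300 days, while the 9 brown adipocyte genes had medians of -0.41 and 0.03, and -0.13 at 700 days. The 15 lymph node genes seen before listing had a median of 3.81 between 300 and 100 days in controls, and the 9 written without sight of their values one of 2.52. Ms4a1 and Cd5 among those 9 were also on the fixed B and plasma cell and T and NK cell lists.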
